A study of Mus musculus with 46 samples.

How the data were processed

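The samples were livers of female WT and PA mice, with 46 samples in all, of which 38 ChIP-seq libraries had a peak list and 8 inputs were not used. Each deposited file lists enriched regions of 1 library by chromosome, start and end. Per the file contents, the deposited positions are in base pairs on GRCm38 (mm10), with no count, score or p-value per region and no region shorter than 500 bp. Per the submitters' processing notes, cutadapt 3.5, Bowtie2 2.5.1, SAMtools 1.17, HOMER 4.10, bedtools 2.31.0 and R 4.1.2 were used, with no role or parameters given. The settings of the peak caller, any use of the inputs, and the read depth are not given in the sources used here. The libraries held 16368 to 70887 peaks. Since depth is unknown, a region without a peak is read as not listed, not as unmarked.

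Groups came from the sample labels: genotype, antibody, preparation letter (A or B) and replicate number. The labels do not say whether A and B of the same number come from the same liver. Rows on chromosome Y (20 in 18 libraries) were removed. The 9 antibodies with both genotypes, 36 libraries, entered the comparisons. Gene positions were those of a RefSeq gene table for GRCm38.p6 with 21631 protein-coding genes on the chromosomes used. That table gives no strand, which changed the plan: the window of 2.5 kb on each side of a transcription start was replaced by the same window at whichever end of the gene had the higher mean coverage over all 38 libraries. For 2957 genes both ends carried over 1000 bp on average, and for them the choice of end is least certain. The window cannot hold more than 5000 bp, so genes that are fully covered cannot rise. All 461 symbols of the 28 gene lists were found in the table.

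Peak number, covered length and the share of peaks that overlap the 2 kb centred on a gene end were compared by exact two-sided permutation of genotype labels, within preparations A and B for the mean over antibodies. Regions were merged over the 4 libraries of an antibody, and a library had a region if at least 1 bp overlapped. Jaccard indices were computed on covered bases. For equal numbers of peaks, only the widest peaks of each library were kept, as many as the smallest library compared held. Covered base pairs per window were averaged over antibodies for each preparation and fitted with limma 3.58.1 in R 4.3.3 (trend, genotype and preparation letter). Genes with a covered base in at least 2 of the 36 libraries were kept. Single antibodies and differences of acyl minus acetyl were fitted with limma and the trend on genotype alone. Acyl against acetyl marks were fitted on genotype and mark. In these fits a gene needed a covered base in at least 2 of the libraries used. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

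The fits were tested on simulated data. With the spread of the pooled values, 0% of changes of 500 bp, 17.9% of 1000 bp and 75.8% of 2000 bp were recovered over 15225 genes, with 1 false call among 63. That spread was taken about the preparation letters only and still held the real differences between the genotypes. The real fit removes them, so these shares tend to understate recovery. At 2 against 2 in single antibodies recovery was between 0% and 1%.

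Named genes followed a rule fixed before the data were examined: Pcca first, the 10 largest increases and 10 largest decreases past the threshold in the pooled fit, the 3 largest in each direction per antibody and per acyl and acetyl pair, 2 to 4 members by smallest unadjusted p of each list described, and the longest region per antibody and direction. Called members beyond these and Pccb, Mmut and Alb were added later. Lists without calls outside the pathways and cell types of interest were only counted. Predicted genes were counted but not named, and 1 gene that the rule selected among the increases and 1 list member were left out of the texts and figures, so 19 genes of the pooled fit are named. Alternatives fixed in advance were a window of 5 kb on each side, quantile normalization, equal numbers of peaks, no filter, limma without the trend, a replicate block, no preparation term, acyl or acetyl marks only, a spread shared between antibodies, other set tests, other peak thresholds and merging, and leaving out each replicate. Alternatives added later were whole genes, both gene ends, averaging A and B, the antibodies of 1 preparation letter, a crossed block, and leaving out H4K16ac.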

Results

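Histone acylation was profiled by native ChIP-seq in frozen livers of female mice on the FVB background at 11 weeks of age. Wild-type (WT) mice were compared with PA mice, which carry a hypomorphic allele of Pcca (A138T) and model propionic acidemia. Pcca encodes the alpha subunit of propionyl-CoA carboxylase, the mitochondrial enzyme that removes propionyl-CoA. Antibodies against H3K9ac, H3K27ac, H4K16ac and H4K16bu (butyrylation) were used on liver preparations labelled A. Antibodies against H4K5ac, H4K5pr (propionylation), H4K12ac, H4K12pr and H4K16pr (Thermo) were used on preparations labelled B. Each of these 9 antibodies had 2 WT and 2 PA libraries, and an in-house H4K16pr antibody had 2 WT libraries. The 38 libraries held between 16368 and 70887 peaks each. Read depth behind the peaks is not given in the sources used here, so no counting interval can be attached to a peak. The 8 input samples were not used here.

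The first question was whether the targeted locus differed in its marks. Pcca lies on chromosome 14 from 122484365 to 122889944 (GRCm38) and carried between 7 and 20 peaks in each of the 36 libraries of the 9 antibodies. Peaks covered 18891 ± 2227 bp of Pcca in WT and 17872 ± 1424 bp in PA (SD over n = 4 preparations each, mean over antibodies; exact two-sided permutation p = 0.5). The main marked region of Pcca, from 122533032 to 122537890, was covered in 18 of 18 WT and 18 of 18 PA libraries, over 4564 ± 841 bp in WT and 4603 ± 264 bp in PA (SD over libraries). The growth protocol label names the variant A138T, an amino acid change, which peak coverage cannot show. Coverage of Pcca was not used to check the genotype labels.

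The extent of each mark was compared between the genotypes next. Peaks of H4K16ac covered 61.3 Mb of the genome in WT and 110.5 Mb in PA livers (means of 2 libraries; WT 74.8 and 47.8 Mb, PA 116.4 and 104.6 Mb), and the ratio of the geometric means was 1.85. H4K5pr covered 102.9 Mb in WT and 134.3 Mb in PA, H4K5ac covered 116.0 and 150.0 Mb, and H4K16pr (Thermo) covered 90.1 and 115.7 Mb. The smallest ratios of geometric means were those of H3K9ac (1.05, arithmetic means 113.3 and 119.4 Mb) and H4K16bu (1.09, arithmetic means 102.0 and 111.7 Mb). The mean of the 2 PA libraries was above that of the 2 WT libraries for all 9 antibodies, and both PA libraries exceeded both WT libraries for 8 of the 9, H4K16bu being the exception. Without PA replicate 2 the H4K16bu difference was -0.05 on the log2 scale. Averaged over antibodies, covered length was higher in PA by 0.32 and peak number by 0.22 on the log2 scale (ratios 1.25 and 1.16; n = 4 preparations per genotype). Each of these had an exact two-sided permutation p of 0.0556, the smallest this design allows if all preparations are separate livers. If A and B of the same number come from 1 liver, the comparison is 2 against 2. The smallest possible p is then 0.333, as it is within 1 antibody. The H4K16ac library of WT replicate 2 held 32358 peaks, the fewest of the libraries compared.

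**Figure D1:**
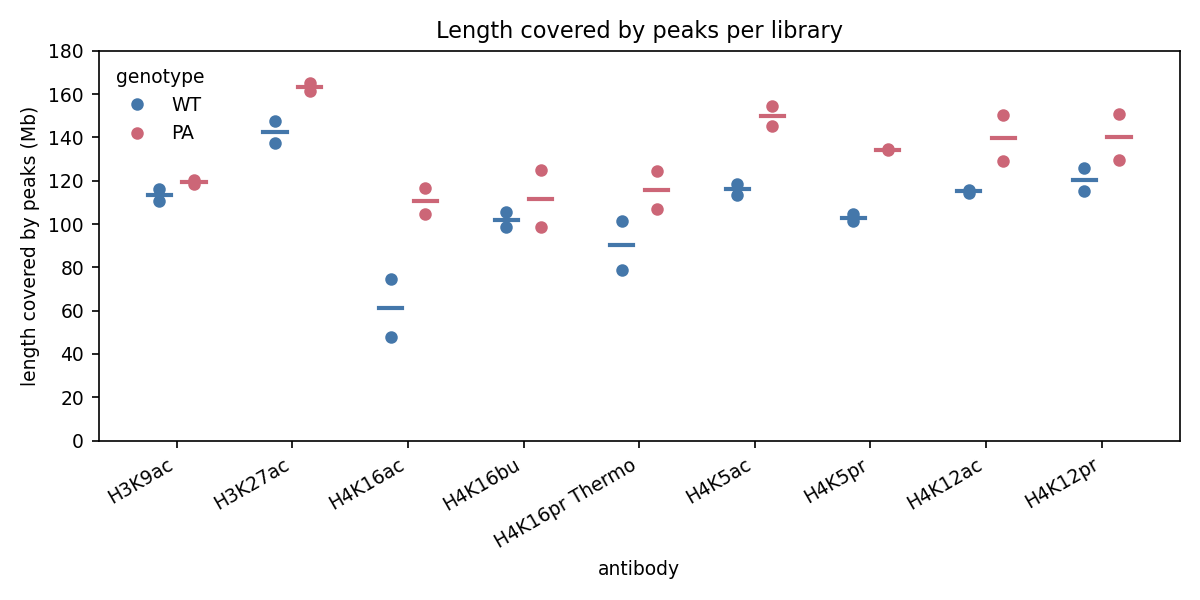
Length of the genome covered by peaks in each library (vertical axis, Mb) for the 9 antibodies (horizontal axis). Points are single libraries of WT and PA livers and short bars are the means of 2. Both PA points lie above both WT points for 8 of the 9 antibodies, and the widest gap is that of H4K16ac.

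The share of peaks at genes showed where each mark lay. Peaks within 1 kb of an end of a protein-coding gene made up 26.3% ± 1.78 of the H4K16pr (Thermo) peaks and 25.9% ± 1.2 of the H4K16bu peaks (SD, n = 4 libraries). The share was lowest for H4K5ac (19.8% ± 1.31) and H3K27ac (20.0% ± 0.593). At H4K5 the propionyl mark had a share of 23.7% ± 1.64. In PA the share was lower for 9 of 9 antibodies, with a mean difference of -2.17 percentage points (24.2% in WT and 22% in PA; exact permutation p = 0.0556, n = 4 preparations per genotype). That p also takes A and B of the same number as separate livers, and 2 against 2 it could not fall below 0.333. The largest difference was that of H4K16ac, from 26.6% to 21.5%. The share is taken over all peaks of a library, and mean peak number was higher in PA for 9 of 9 antibodies. A lower share therefore does not mean fewer peaks at gene ends.

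Overlap of the covered bases was higher between libraries of the same genotype than between genotypes for 9 of 9 antibodies. The difference in mean Jaccard index was largest for H4K16ac (0.492 within and 0.409 between) and H4K5pr (0.682 and 0.617). It was smallest for H4K12pr (0.584 and 0.561) and H3K27ac (0.624 and 0.601). For 7 of the 9 antibodies both within-genotype pairs exceeded every between-genotype pair. With equal numbers of peaks this no longer held for H3K27ac (WT pair 0.6162, highest between-genotype pair 0.6170) and H4K12pr (0.581 and 0.586). Between marks of the same preparations, H4K5pr overlapped H4K12ac most (0.695 ± 0.00971, SD over 4 preparations), and H3K27ac overlapped H4K16ac least among the pairs with 4 preparations (0.452 ± 0.112).

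Regions marked in both livers of one genotype and in neither of the other were then located. H4K16ac had 6890 regions found in PA only and 456 found in WT only, and H4K5pr had 5281 and 781. H3K9ac had 2812 in PA only and 1897 in WT only, the smallest imbalance together with H4K16bu (2765 and 1751). Regions of PA only outnumbered those of WT only for 9 of 9 antibodies, and they outnumbered the regions shared by any pair of 1 WT and 1 PA library for 9 of 9. Regions of WT only did so for 1 of 9, H3K9ac, where the highest crossed pair had 1687. PA libraries held more peaks on average. Equal numbers of peaks per library were therefore made by keeping only the widest peaks, which does not match read depth. With equal numbers more antibodies joined H3K9ac. WT-only regions then also outnumbered every crossed pair for H4K16bu (1951, highest crossed pair 1400) and H4K5pr (1328 and 1097). H4K12ac (1750 and 1652) and H4K16pr (1070 and 1036) did so by less, and H3K27ac, H4K16ac, H4K5ac and H4K12pr did not. The genotype split gave more regions than both crossed splits of the same 4 libraries for 9 of 9 antibodies, and with 3 splits no p below 0.333 is possible. Requiring coverage of 50% of a region raised the PA-only count of H4K16ac to 10632, and equal numbers of peaks per library lowered it to 2838. With equal numbers H4K16ac had 634 regions in WT only, and H4K5pr had 2922 in PA only and 1328 in WT only. The imbalance between the genotypes was then smaller for both marks.

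Lpl, which encodes lipoprotein lipase, held the longest of these PA-only regions for H4K5pr (chromosome 8, 68877814 to 68884165) and for H4K12ac (68877745 to 68884578). The longest PA-only regions of the other antibodies lay at Pxk (H3K9ac, 11929 bp), Plcl1 (H4K5ac, 10480 bp), Atp6v0e (H4K16bu, 8769 bp), Agap1 (H4K16ac, 8567 bp), Cmip (H4K16pr, 7542 bp), Srgap2 (H3K27ac, 7136 bp) and Tcf12 (H4K12pr, 5740 bp). Cmah, which encodes the enzyme that makes N-glycolylneuraminic acid, held the longest WT-only region of H4K5ac (chromosome 13, 24373087 to 24380846), of H4K12ac (6475 bp) and of H4K12pr (6847 bp). A region on chromosome 5 from 33456657 to 33467742, 22566 bp from Nkx1-1, was the longest WT-only region of H3K27ac, and overlapping regions were the longest of H4K16pr (8210 bp) and H4K5pr (10191 bp). The longest WT-only region of H4K16ac (4319 bp) lay 4962 bp from Mup-ps16 in the cluster of major urinary protein genes, that of H4K16bu (8215 bp) 1629 bp from Spin1, and that of H3K9ac (7057 bp) at Ube2v1. Gaps in the deposited H3K9ac peak lists, described below, may account for the H3K9ac regions at Pxk and Ube2v1.

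**Figure D2:**
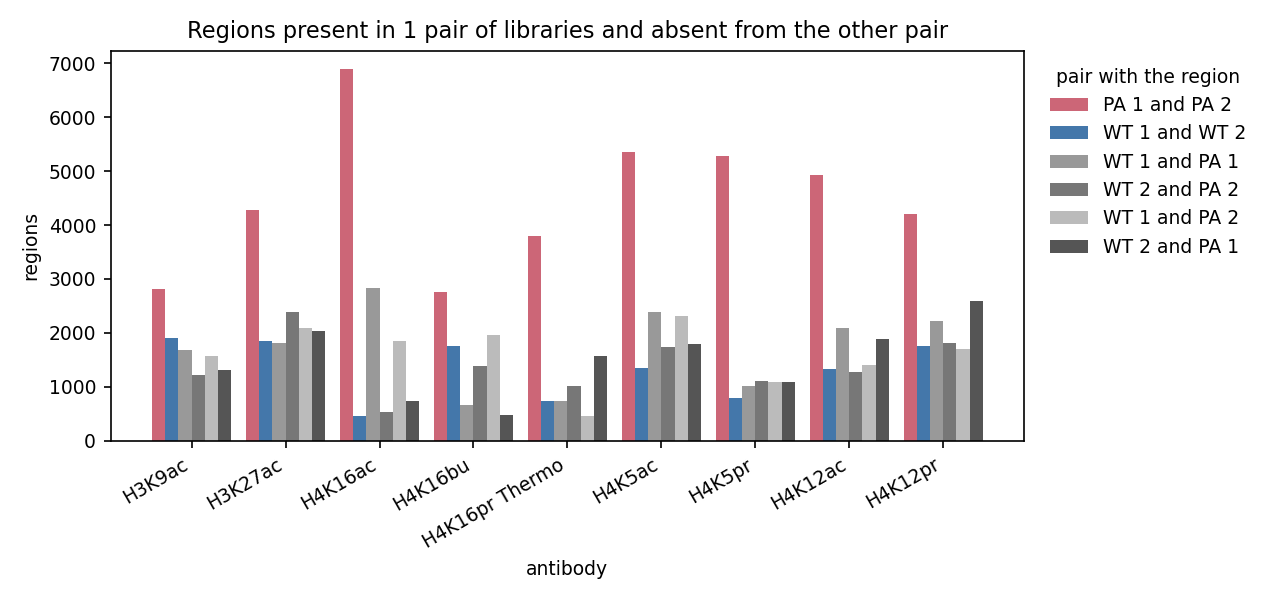
Number of regions (vertical axis) present in both libraries of a pair and absent from the other pair, for each antibody (horizontal axis). Coloured bars are the genotype pairs and grey bars are the 4 pairs of 1 WT and 1 PA library. The bar of the PA pair is the highest for 9 of 9 antibodies.

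Coverage of gene ends by all marks together was compared between PA and WT for each gene. Each value is the number of base pairs covered by peaks in a 5000 bp window at a gene end, averaged over the antibodies of a liver preparation (n = 4 WT and 4 PA preparations; values below are means ± SD). Coverage at Cfap44, a gene of cilia and flagella, was 51.3 ± 77.9 bp in WT and 4198 ± 685 bp in PA (limma adjusted p = 0.00265). Lpl rose from 474 ± 492 to 4479 ± 567 bp (limma adjusted p = 0.00312), and Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, from 1556 ± 618 to 4242 ± 569 bp (limma adjusted p = 0.00899). Hsd3b5, a male-biased gene of steroid metabolism, fell from 2744 ± 477 to 149 ± 128 bp (limma adjusted p = 0.00265). Slco1a1, an organic anion transporter of hepatocytes, fell from 4829 ± 144 to 2370 ± 301 bp (limma adjusted p = 0.00141).

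Other genes with large increases included the glutathione transferase Gstm3 (1945 ± 678 to 4896 ± 129 bp) and the efflux transporter Abcc4 (1807 ± 772 to 4744 ± 229 bp). They also included the complement regulator Cd46, the sulfotransferases Gal3st1 and Sult2a3, and the splicing regulator Srrm4, each higher by between 2238 and 2745 bp. The largest decreases were those of the cytochrome P450 gene Cyp3a44 (2852 ± 320 to 204 ± 330 bp) and of Sult3a1 (3074 ± 455 to 434 ± 351 bp), both female-biased. Sult5a1 fell from 4590 ± 347 to 1974 ± 554 bp. Cyp3a16 fell from 1792 ± 420 bp and was listed at 0 in all 4 PA preparations. Irf5, a transcription factor of innate immunity, fell from 4413 ± 270 to 2503 ± 412 bp, and Spatc1l from 3037 ± 481 to 1156 ± 471 bp. Mup-ps16 (3433 ± 173 to 912 ± 978 bp) and Mup19 (2866 ± 245 to 892 ± 938 bp) have overlapping windows, so their decreases are not independent. Values of the Mup, Cyp3a, Sult and Gstm genes are uncertain, since members of these families are alike in sequence and reads could be shared between them. For the genes with increases named here the PA mean was higher in 9 of 9 antibodies, and for the 10 with decreases it was lower in 9 of 9, except Sult3a1 with 8. These genes were chosen on the mean over the same antibodies, so this agreement is not independent support.

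**Figure D3:**
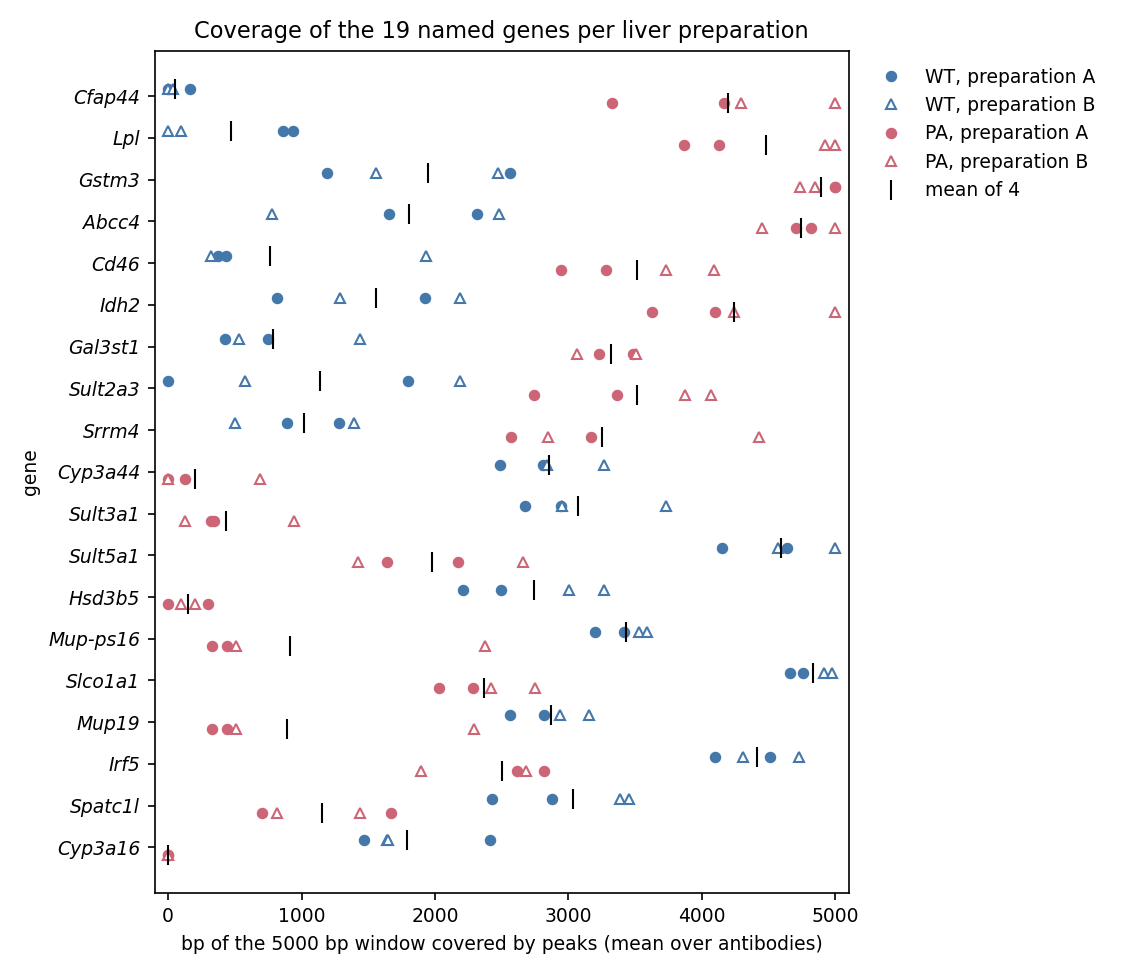
Base pairs of the 5000 bp window covered by peaks (horizontal axis, mean over antibodies) for the 19 named genes (vertical axis). Symbols are the 4 WT and 4 PA liver preparations, filled circles for A and open triangles for B, and black ticks are the means of 4. The WT and PA preparations of Slco1a1 lie between 4663 and 4977 bp and between 2028 and 2750 bp.

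Of 15225 genes tested, 686 were higher and 39 lower in PA (limma with a term for the preparation letter, Benjamini-Hochberg adjusted p under 0.05). Without H4K16ac 213 were higher and 27 lower. The antibodies of preparation A alone or of preparation B alone, 2 against 2, gave 0 in either direction. The median gene was higher in PA by 245 bp, and after quantile normalization between preparations the median shift was -16.6 bp and 145 genes were higher and 84 lower, among them 145 of the 686 and 39 of the 39. The labels do not say whether preparations A and B of the same number come from 1 liver, and the correlation of their deviations from the group mean across genes (r = 0.173 for WT 1A with WT 1B, 0.0591 for PA 1A with PA 1B) does not settle it. With them averaged, 2 against 2, limma called 0 genes (3874 at unadjusted p under 0.05, smallest adjusted p 0.0723), and leaving out 1 preparation gave 287 (WT 1A), 181 (WT 2A), 250 (PA 1A), 183 (PA 2A), 225 (WT 1B), 241 (PA 1B) or 1201 (PA 2B) genes higher and 21 (WT 2A), 20 (PA 1A) or 22 (PA 2A) lower.

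Gene lists fixed before the data were examined were tested as groups with limma's camera, and their members with limma. Among 14 male-biased liver genes 3 fell and 1 rose over all genes tested, and the counts adjusted over the list alone were the same. Those that fell were Slco1a1, Hsd3b5 and Cyp7b1, the oxysterol hydroxylase of bile acid synthesis (3995 ± 419 to 2788 ± 233 bp), and the one that rose was Cyp2d9 (2551 ± 637 to 3634 ± 310 bp). The list shifted down relative to the other genes (camera adjusted p = 7.09e-07; adjusted p = 0.137 with an estimated correlation). Its median difference was -27.25 bp, with 7 of the 14 members higher and 7 lower in PA. Only the 3 that fell were lower at unadjusted limma p under 0.05, so the fall was not list-wide. Among 15 female-biased genes 3 rose (Hao2, 1358 ± 346 to 2901 ± 242 bp; Cux2, 1807 ± 851 to 3299 ± 525 bp; Sult2a1, 851 ± 656 to 2333 ± 253 bp) and 2 fell (Cyp3a44 and Sult3a1). Adjusted over the list alone, 7 rose and 4 fell, and the list as a group did not pass (camera adjusted p = 0.204).

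Genes of xenobiotic metabolism shifted up as a group, with 6 of 20 members higher and none lower (8 higher when adjusted over the list alone). The shift had a camera adjusted p of 0.0289, and adjusted p = 0.794 with an estimated correlation. It did not pass with whole genes (camera adjusted p = 0.258) or without preparation WT 1A, WT 2A, PA 1A, PA 2A or PA 2B (0.0681 to 0.136). The 6 higher members are Gstm3, Gstm1 (4005 ± 113 to 4757 ± 129 bp), Cyp2a5 (3560 ± 431 to 4656 ± 182 bp) and Nqo1, a quinone reductase (2707 ± 394 to 3783 ± 235 bp), with Gsta3 (4284 ± 203 to 4919 ± 163 bp) and Gsta1 (844 ± 573 to 2219 ± 162 bp) the other 2. Of 14 genes of bile acid synthesis and transport, Slco1a1 and Cyp7b1 fell, and Abcb11, the bile salt export pump, rose only when adjusted over the list alone (3773 ± 212 to 4233 ± 54.5 bp). That list shifted down relative to the other genes (camera adjusted p = 0.0151; adjusted p = 0.575 with an estimated correlation and 0.0534 after quantile normalization), although its median difference was 85.7 bp higher in PA.

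Pathways that use propionyl-CoA and its neighbours showed few calls. Of 15 genes of propionate and methylmalonate metabolism, 0 passed limma over all genes and 1, Aldh6a1 (3306 ± 534 to 3966 ± 370 bp, unadjusted p = 0.0033), rose when adjusted over the list alone. Pcca itself is in that list, and its window, at a gene end, does not hold the main marked region of the gene and was nearly empty (168 ± 203 and 25 ± 50 bp), so the list count says nothing about Pcca. Other members that did not pass included Hibadh (3593 ± 274 and 4034 ± 110 bp), Pccb (4105 ± 222 and 4384 ± 116 bp) and Mmut, the methylmalonyl-CoA mutase (2661 ± 181 and 2820 ± 164 bp). Of 17 genes of branched-chain amino acid breakdown, Dbt rose (2701 ± 152 to 4027 ± 133 bp), and 5 rose when adjusted over the list alone, with Ivd and Bckdk among them. In the tricarboxylic acid cycle, Idh2 and Ogdh (3166 ± 324 to 4022 ± 181 bp) rose among 18 genes, and 6 rose when adjusted over the list alone. Neither the propionate, the branched-chain nor the tricarboxylic acid list passed as a group with camera (adjusted p = 0.990, 0.576 and 0.440). With fry, which does not compare a list with the other genes, the last 2 were higher in PA (adjusted p = 0.0315 and 0.0460).

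Among 20 PPARA targets and ketogenesis genes, Vnn1 (2382 ± 321 to 3405 ± 458 bp), Fgf21, a fasting hormone of the liver (3416 ± 444 to 4519 ± 271 bp), and Cyp4a10 (4068 ± 452 to 4946 ± 47.8 bp) rose, and 5 rose when adjusted over the list alone. As a group these 20 did not pass (camera adjusted p = 0.0650) except after quantile normalization (adjusted p = 0.0184), with fry (0.0315) and without preparation WT 1B (0.00473) or PA 1B (0.0289), each time up. Cps1, the first enzyme of the urea cycle, rose among 10 genes (3366 ± 126 to 4392 ± 237 bp), and Glul joined it when adjusted over the list alone, with 2 higher in all. Ppargc1a, a coactivator of gluconeogenesis, rose from 25 ± 50 to 624 ± 231 bp and was the only one of 12 gluconeogenesis genes called, while Pck1 did not pass (4556 ± 266 and 4826 ± 121 bp). Of 16 genes of mitochondrial fatty acid oxidation, 16 of glycolysis and lipogenesis and 16 of oxidative phosphorylation, 0 passed limma over all genes or adjusted over the list alone (2, 2 and 7 at unadjusted p under 0.05, all with higher means in PA). Among their smallest p values were those of Slc25a20 (2852 ± 184 and 3332 ± 218 bp) and Etfa (3575 ± 105 and 4115 ± 439 bp), of Me1 (3938 ± 108 and 4579 ± 500 bp), and of Uqcrfs1 (2821 ± 170 and 3393 ± 177 bp) and Cyc1 (2129 ± 212 and 2651 ± 235 bp). At unadjusted p the smallest list p among these 3 groups was 0.0122, for glycolysis and lipogenesis (down, camera adjusted p = 0.0569), a list that passed, down relative to the other genes, with whole genes (adjusted p = 0.000119) and without WT 1A (0.0357) or PA 1B (0.0257). Fdft1 (3180 ± 379 to 4449 ± 365 bp) and Fdps (4349 ± 179 to 4696 ± 277 bp) rose among 19 genes of cholesterol synthesis, where 3 rose when adjusted over the list alone.

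Stress and inflammation genes moved singly. Lcn2 (1684 ± 368 to 3044 ± 166 bp), Apcs and Saa2 (562 ± 228 to 1639 ± 537 bp), all acute phase genes, rose among 18, and 4 rose when adjusted over the list alone. In the integrated stress response list Ddit4 (4044 ± 209 to 4689 ± 125 bp) and Phgdh (945 ± 911 to 1694 ± 730 bp) rose among 17 genes. Chac1 fell when adjusted over the list alone (3673 ± 490 to 1561 ± 1003 bp). Npas2 rose among 17 circadian clock genes (1057 ± 334 to 1886 ± 105 bp), and Clock did not pass (3256 ± 558 and 4198 ± 258 bp). None of these 3 groups passed as a list with camera (adjusted p = 0.949, 0.204 and 0.850), and the clock list was higher in PA with fry (adjusted p = 0.0366).

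Marker genes of other liver cell types were measured in the same windows. The Kupffer cell and macrophage list shifted down, with a median difference of -145 bp (camera adjusted p = 7.09e-07; adjusted p = 0.137 with an estimated correlation), while 0 of its 14 members passed limma (1 at unadjusted p under 0.05). Cd14 (1731 ± 144 and 1233 ± 380 bp), Cd68 (3988 ± 611 and 4483 ± 245 bp) and Spi1 (1823 ± 889 and 1244 ± 352 bp) had its smallest p values. The lymphocyte list shifted down relative to the other genes, with a median of -32.0 bp (camera adjusted p = 0.00507, 0.606 with an estimated correlation and 0.187 after quantile normalization). It also missed the threshold without preparation WT 1A (camera adjusted p = 0.0980), WT 2A (0.0750) or PA 1A (0.0656). Of its 12 members 0 passed limma. The 2 at unadjusted p under 0.05, Ccr7 (1170 ± 300 and 1903 ± 595 bp) and Cd3g (485 ± 178 and 706 ± 106 bp), had higher means in PA, as did 5 of the 12 in all. Flt4 rose among 14 endothelial markers (742 ± 687 to 1627 ± 521 bp; Lyve1, not passing, 3383 ± 775 and 4369 ± 473 bp) and Sox9 among 8 cholangiocyte markers (1877 ± 207 to 2918 ± 372 bp), where Elf3 did not pass (940 ± 209 and 1457 ± 262 bp). Of 20 hepatocyte identity genes 0 passed limma (3 at unadjusted p under 0.05, with Nr5a2 at 4167 ± 134 and 4629 ± 149 bp and Hnf4a at 3594 ± 572 and 4264 ± 277 bp), and the window was close to full for most, as at Alb (4451 ± 186 and 4485 ± 391 bp). In the lists of lysine acylation enzymes and readers, cell proliferation, stellate cells and housekeeping 0 genes passed limma (1, 4, 0 and 7 at unadjusted p under 0.05). Adjusted over the list alone, 2 of the 16 housekeeping genes rose. Their median difference was 452 bp, against 328 bp for branched-chain breakdown and 338 bp for the tricarboxylic acid cycle. Rises adjusted over the list alone are therefore not particular to the metabolic lists. Over all lists 28 of 416 measured genes rose and 5 fell. After quantile normalization 5 of the 28 (Dbt, Idh2, Gstm3, Cyp2a5 and Hao2) and 5 of the 5 stayed past the threshold.

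Each antibody was also tested alone, 2 PA against 2 WT libraries. H3K9ac was the only antibody with calls, 29 genes higher and 21 lower in PA (limma; 1348 of 14149 genes at unadjusted p under 0.05). Pxk (0 to 5000 bp), Kcmf1 (95.0 to 5000 bp) and Stard7 (0 to 4768 bp) had the largest increases, with limma adjusted p of 0.0253, 0.0261 and 0.0465. Ube2v1 (5000 to 0 bp), Slc25a28 (4110 to 0 bp) and Pex7 (3869 to 0 bp) had the largest decreases, with limma adjusted p of 0.0253, 0.0460 and 0.0460. These H3K9ac windows were covered over at least 3869 bp in one genotype and at most 95.0 bp in the other, and crossed pairs of the H3K9ac libraries gave windows of the same kind. Without PA replicate 1 or PA replicate 2, 0 genes were called in H3K9ac, and without WT replicate 1 or WT replicate 2 the counts were 126 and 97 higher and 0 lower.

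For the other 8 antibodies limma called 0 genes, with between 923 (H4K12pr) and 2958 (H4K16ac) genes at unadjusted p under 0.05. The mean difference over genes was 812 bp higher in PA for H4K16ac, 456 bp for H4K16pr (Thermo), 393 bp for H4K5pr and 93.5 bp for H3K9ac. On simulated libraries with the spread of each antibody, between 0% and 1% of changes of 2000 bp were recovered, so a lack of calls at this size says little about a single mark. With the spread shared between the antibodies of a preparation letter, 2827 genes were higher and 21 lower for H4K16ac and 271 and 46 for H4K5ac. Whether the genotype difference differed between antibodies was tested only for the acyl and acetyl marks of the same residue.

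Acyl and acetyl marks of the same residue were compared to ask where they part. Fga, which encodes a fibrinogen chain, was covered over 4588 ± 824 bp by H4K16bu and 619 ± 619 bp by H4K16ac (n = 4 libraries each; limma adjusted p = 0.0186). Slc25a33 (4773 ± 454 and 1317 ± 620 bp) and Elovl2, an elongase of polyunsaturated fatty acids (4543 ± 307 and 1098 ± 561 bp), were wider in H4K16bu too. Ndrg3 was wider in H4K16ac (2388 ± 176 and 4238 ± 261 bp). In all, 158 genes were wider in H4K16bu and 1 in H4K16ac (2891 at unadjusted p under 0.05), and 9 and 3 after quantile normalization. Marks of a preparation come from the same liver, and with the preparation as a block 0 and 0 genes passed (2603 at unadjusted p under 0.05). Wider H4K16bu was called at 84 genes without PA replicate 1 and at 0 without PA replicate 2, WT replicate 1 or WT replicate 2.

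At H4K5, Gpihbp1, the endothelial anchor of lipoprotein lipase, was covered over 3134 ± 345 bp by H4K5pr and 281 ± 329 bp by H4K5ac (limma adjusted p = 0.0289, n = 4 libraries each). Clec4g, a lectin of liver sinusoidal endothelium, was covered over 2545 ± 135 bp by H4K5pr and was listed at 0 in all 4 H4K5ac libraries (limma adjusted p = 0.00173). Fli1, a transcription factor of endothelial and blood cells, had 2629 ± 669 and 250 ± 500 bp. Csrp3 (1506 ± 442 and 4209 ± 408 bp), Clec2e (489 ± 596 and 2970 ± 483 bp) and Hopx (893 ± 342 and 2565 ± 225 bp) were wider in H4K5ac. In all, 16 genes were wider in H4K5pr and 8 in H4K5ac (limma; 1860 at unadjusted p under 0.05), against 4 and 3 after quantile normalization. With the liver preparation as a block 0 genes passed (2153 at unadjusted p under 0.05), and leaving out any of the 4 WT and PA replicates in turn left 0.

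At H4K12 limma called 0 genes in either direction between the propionyl and acetyl marks (899 at unadjusted p under 0.05, smallest adjusted p 0.215), and 0 with the preparation as a block (1324 at unadjusted p under 0.05). Elovl2 (4669 ± 418 and 1098 ± 561 bp), Gclc, a subunit of the first enzyme of glutathione synthesis (4351 ± 770 and 1156 ± 1067 bp), and Slc25a33 (4489 ± 605 and 1317 ± 620 bp) were wider in H4K16pr (Thermo) than in H4K16ac. They were among 51 genes wider in H4K16pr and 0 wider in H4K16ac (limma; 2445 at unadjusted p under 0.05; 20 wider in H4K16ac after quantile normalization). H4K16pr came from preparations B and H4K16ac from preparations A, so the mark and the preparation cannot be told apart for these 51 genes, and leaving out any of the WT and PA replicates in turn left 0.

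The genotype difference of an acyl mark was compared with that of the acetyl mark of its residue. Limma called 0 genes for H4K5pr minus H4K5ac, H4K12pr minus H4K12ac and H4K16bu minus H4K16ac, with 813, 898 and 1213 genes at unadjusted p under 0.05 (n = 2 preparations per genotype, smallest adjusted p 0.777, 0.784 and 0.524). The mean of this difference over genes was 68.2 bp at H4K5, -6.13 bp at H4K12 and -527 bp for H4K16bu against H4K16ac. These means were not tested. In the last of them the acetyl mark had the larger PA minus WT difference. It includes the H4K16ac library of WT replicate 2, which held 32358 peaks over 47.8 Mb, against 46402 over 74.8 Mb in WT replicate 1. A wider acetyl mark in PA and a thin WT library cannot be told apart there. The genes with the smallest p were Ms4a18 (-2069 bp, H4K5), Adamts10 (2464 bp, H4K12) and Cln3 (-2844 bp, H4K16).

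Peaks of the H4K16pr antibodies were compared in the same WT livers. In WT preparation 1B, 59.6% of 38617 Thermo peaks overlapped an in-house peak and 74.1% of 36465 in-house peaks overlapped a Thermo peak (Jaccard index 0.479). In preparation 2B, where the in-house library held 16368 peaks, the shares were 25.8% and 84.0% (Jaccard index 0.138). With equal numbers of peaks in 2B, 55.8% of Thermo peaks overlapped. With equal numbers of peaks, in-house peaks overlapped Thermo H4K16pr peaks by 73.5% in 1B and 74.0% in 2B, and the H4K5 and H4K12 marks by between 75.1% and 77.3% in 1B and between 72.3% and 73.9% in 2B, so overlap of peaks does not single out the residue. The Jaccard index of the in-house library was highest with Thermo in 1B (0.400 or less with the H4K5 and H4K12 marks) and in 2B (0.134 or less). Of these lists Thermo also covered the least length, 78.7 Mb in 1B and 101.5 Mb in 2B. H4K5pr had the next highest index and covered the next least (101.3 and 104.5 Mb). The order of the Jaccard index therefore cannot be told apart from the covered length of the lists. The in-house antibody has WT libraries only, so no genotype comparison was made with it.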

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

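The tests for gaps in the H3K9ac lists, for depth as the cause of the calls, for the H4K16ac library and for a male liver, and the splits of the last paragraph, were chosen after the result was seen. Of 43 groups of 4 preparations checked for a sample far from the others, 4 had one, and chance gives about 5% of groups. Preparation WT 2A had the lowest peak number of the WT preparations, a mean log2 of 15.47. WT 2B stood above the other WT preparations at Cd46 (1932 bp). PA 2B stood above the other PA preparations at Mup-ps16 (2375 bp) and at Mup19 (2295 bp), whose windows overlap. A signal in data not used elsewhere was the 20 regions on chromosome Y in 18 libraries of female mice, 10 in WT and 10 in PA libraries. All started between 90744254 and 90798755, at the end of the chromosome that it shares with X.

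At 39 genes coverage was lower in PA, among them the male-biased genes Slco1a1, Hsd3b5 and Cyp7b1 and the female-biased genes Cyp3a44 and Sult3a1. Reads shared between near-identical gene copies could lower a family together, but 56.4% of the 39 genes (22, such as Cyp7b1, Irf5 and Cmah) had no protein-coding gene with the same leading letters in its symbol within 1 Mb, which argues against this as the whole cause. A male liver in the WT group would bring peaks at Y-linked genes, and 0 peaks lay within 5 kb of Kdm5d, Eif2s3y, Uty or Ddx3y in the 38 libraries. A homozygous deletion of the windows in the PA line and a lower level of the marks cannot be told apart for part of the genes, since 46.2% of the 39 (18 genes) kept at least 500 bp covered in each PA preparation. The cause of the lower coverage stays open.

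In PA, coverage was wider over most genes, with a median shift of 245 bp. Quantile normalization removed the shift and kept 184 of the 725 gene calls, so a shift common to all windows is not their whole cause. It cannot remove effects of depth or enrichment that differ between windows. With read depth unknown, depth or enrichment as a cause of the gene calls stays open. As the cause of the median shift itself, depth and genotype cannot be told apart. With equal numbers of peaks the shift was 229 bp, but that setting dropped only the narrowest peaks. Peak widths still differed and read depth was unknown. The H4K16ac library of WT replicate 2 may add to the shift, but without H4K16ac it was 185 bp, so this library is not its whole cause.

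In H3K9ac, 17 windows were covered over at least 3500 bp in both libraries of a genotype and empty in both of the other. Gaps in the deposited H3K9ac peak lists may account for these, since a crossed pairing of WT with PA libraries gave 19 such windows and the other crossed pairing gave 11, while no other antibody had over 2 in the genotype pairing. Of the 50 genes called in H3K9ac, 70% (35) shifted the same way in the mean of the other 3 marks of the same preparations, short of the 75% set in advance for a shared change of active chromatin. Whether part of these calls reflects a genotype change of the other marks too cannot be told apart from gaps at this number of libraries.

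For the pooled comparison the 18 splits that exchange genotypes within a preparation letter are too few for a share under 0.05. The real split gave 725 calls and the highest of the other splits 0 (1 of 18 splits gave as many). If A and B of the same number come from 1 liver the design is 2 against 2, and with A and B averaged limma called 0 genes (3874 at unadjusted p under 0.05). For H4K16pr against H4K16ac, where the mark is confounded with the preparation letter, the 18 splits that exchange marks within a genotype are too few as well (51 calls, highest other 0). The other acyl and acetyl marks came from the same 4 preparations, and the 8 splits that exchange marks within preparations are again too few. The real split gave 24 calls for H4K5pr against H4K5ac and 159 for H4K16bu against H4K16ac, and the highest other split gave 0 for each. With the preparation as a block limma called 0 genes for both (2153 and 2603 at unadjusted p under 0.05). For H4K12pr against H4K12ac the real count was 0, so 8 of 8 splits gave as many by construction and the splits say nothing about chance.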

How the results depend on the processing

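Tests chosen after the data were seen were whole genes, both gene ends, averaging preparations A and B, the antibodies of 1 preparation letter, a crossed block and leaving out H4K16ac; the others were fixed in advance. Peak number and the share of peaks at gene ends kept their direction under every alternative tried. The overlap of libraries had 1 alternative per antibody, equal numbers of peaks, and kept its direction there. Under it H3K27ac and H4K12pr no longer had both within-genotype pairs above every between-genotype pair. Covered length kept its direction in 73 of 74 comparisons. The exception was H4K16bu without PA replicate 2, at -0.051 on the log2 scale (leave-one-out range -0.051 to 0.29), where PA replicate 2 had covered the most. None of these values can pass a threshold at this size, so only direction was compared. The 19 named genes kept their sign in all 399 refits and their call in 343. They were chosen for large differences in the same data, so a kept sign is not independent support. Acyl marks only ended 7 calls, leaving out 1 preparation 0 to 4, leaving out H4K16ac 3, acetyl marks only and a replicate block 2 each, quantile normalization 1, and averaging A and B all 19, where fewer samples were tested. Peaks carry no score or depth, which limits every value here to presence and width; the cause of the other changes below was not tested.

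For the pooled gene ends (686 higher, 39 lower in PA), 2005 and 90 passed with a window of 5 kb on each side, 145 and 84 after quantile normalization, 95 and 11 with acyl marks only, 293 and 25 with acetyl marks only, and 398 higher without the preparation term. Added later, whole genes gave 3423 and 147, both gene ends 1314 and 63, leaving out H4K16ac 213 higher, and averaging A and B, the antibodies of preparation A alone and those of preparation B alone 0 and 0 each. Leaving out 1 preparation gave 181 to 1201 higher and 20 to 47 lower. A replicate block gave 116 and 19, and 527 and 33 with the numbers crossed in preparation B; replicate numbers are shared between the genotypes, but paired samples were not alike (across genes r = 0.00372 for WT 1A with PA 1A and -0.103 for WT 1B with PA 1B), so the block result is given here only. The number of lists shifted up (1) and down (4) was 0 and 0 with an estimated correlation, 5 and 1 with fry, 2 and 2 after quantile normalization, 0 up for whole genes, and 0 to 2 up when 1 preparation was left out. Quantile normalization ended the calls of the bile acid (adjusted p = 0.0534) and lymphocyte (0.187) lists, whole genes those of the bile acid (0.0683) and xenobiotic (0.258) lists, and fry those of the bile acid (0.0851), Kupffer (0.211) and lymphocyte (0.956) lists. The male-biased and Kupffer lists stayed past the threshold without any 1 preparation. The xenobiotic list missed it without WT 1A (adjusted p = 0.0681), WT 2A (0.0750), PA 1A (0.136), PA 2A (0.113) or PA 2B (0.126), the lymphocyte list without WT 1A (0.0980), WT 2A (0.0750) or PA 1A (0.0656), and the bile acid list without WT 1A (0.0681).

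Genotype-specific regions with equal numbers of peaks were 2838 (H4K16ac), 2309 (H4K16pr), 3532 (H4K5ac), 2922 (H4K5pr) and 3058 (H4K12ac) in PA only and 1328 (H4K5pr) in WT only. With coverage of 50% of the region they were 10632 (H4K16ac), 8235 (H4K5ac) and 8110 (H4K5pr) in PA only. Leaving out a replicate eases the requirement by construction, and the ranges in PA only and WT only were 5089 to 9.8e+03 and 3860 to 7572 (H3K9ac), 7050 to 18282 and 3608 to 10610 (H3K27ac), 8482 to 27054 and 949 to 9747 (H4K16ac), 4390 to 11272 and 2373 to 8134 (H4K16bu), 5078 to 14269 and 1501 to 5083 (H4K16pr), 8632 to 21717 and 2658 to 11510 (H4K5ac), 7928 to 14179 and 1845 to 3975 (H4K5pr), 8015 to 20212 and 2586 to 8049 (H4K12ac), and 7144 to 19171 and 3252 to 11128 (H4K12pr). The H4K16pr antibodies in preparation 2B overlapped by 55.8% and 74.0% with equal numbers of peaks.

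The H3K9ac calls (29 and 21) were 0 and 0 with a window of 5 kb on each side, with whole genes, with both gene ends and with a replicate block, 9 higher without the trend, and 0 to 126 higher and 0 lower with 1 replicate left out. With the spread shared between antibodies the counts higher and lower were 158 and 127 (H3K9ac), 128 and 38 (H3K27ac), 2827 and 21 (H4K16ac), 56 and 31 (H4K16bu), 31 and 2 (H4K16pr), 271 and 46 (H4K5ac), 40 and 5 (H4K5pr), 17 and 9 (H4K12ac) and 22 and 8 (H4K12pr). From 0 and 0, leaving out 1 replicate, whose group then has a lone library assumed to vary like the other group, gave up to 385 and 2 (H3K27ac), 457 and 1 (H4K16ac), 360 and 2 (H4K16pr) and 252 and 1 (H4K5pr). Quantile normalization gave 2 and 1 for H4K16pr, and whole genes 1 higher for H4K12ac.

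Wider acyl and wider acetyl genes were, for H4K5 (16 and 8), 83 and 28 with a window of 5 kb on each side, 4 and 3 after quantile normalization, 4 and 1 without the trend, 4 wider acetyl without a filter, 213 and 193 for whole genes, and 0 and 0 with a replicate block or any 1 replicate left out. For H4K16bu (158 and 1) they were 274 and 4, 9 and 3, 103 wider acyl without the trend, 352 wider acyl with equal numbers of peaks, 1 and 0 for whole genes, 0 and 0 with a replicate block, and 0 to 84 and 0 to 1 with 1 replicate left out. For H4K16pr (51 and 0) they were 177 and 2 with the wider window, 20 wider acetyl after quantile normalization, 219 and 2 with equal numbers of peaks, 143 and 6 for whole genes, and 0 with any 1 replicate left out. H4K12 had 32 and 3 for whole genes. The acyl minus acetyl genotype difference gave 1 gene, at H4K5 with whole genes, and 0 otherwise.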

Other observations

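The tests of this part were all chosen after the genotype-specific regions were seen. Regions found in one genotype only recurred across marks. Merged over antibodies, 492 regions were found in PA only for 5 or more of the 9 antibodies and 99 in WT only, while the 4 pairs of 1 WT and 1 PA library gave 4, 5, 9 and 12 such regions. The region found in PA only for all 9 antibodies lay at Cnot9 and Usp37 (chromosome 1, 74527671 to 74529773). Regions found in WT only for all 9 lay at Dym (chromosome 18, 75116562 to 75123489), at Mrps18a and Rsph9, at Acad9, a member of the acyl-CoA dehydrogenase family (chromosome 3, 36078073 to 36082355), at Mup15, and 22476 bp from Nkx1-1. Among those found for 8 antibodies were Nudt18 and Nck2 in PA only and Cmah, Dntt and Wwox in WT only. Antibodies of the same preparation letter share livers, so these counts describe the livers and are not independent evidence per mark.

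Near Pcca, within 10 Mb on each side, 2 of 24 tested genes rose in PA, Abcc4 and Slc15a1, and 0 fell. Elsewhere 684 of 15201 rose (Fisher's exact p = 0.295, two-sided).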
